A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

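RNA of Saccharomyces cerevisiae, the budding yeast, was measured on 6 single-channel arrays, 3 from a wild-type strain and 3 from a strain whose histone H2B carries the K111A substitution, alanine in place of a lysine. Per the labels' protocols, cells were grown in YPD, a rich glucose medium, to mid-log phase, total RNA was extracted with hot acid phenol, and biotin-labelled cRNA was made from it. The labels number the samples of each strain but do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

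The deposited table holds linear intensity values, and the authors had already brought the arrays to a common scale. The software and the method used for that summary and scaling are not given in the sources used here. The table has 10928 probe sets. The array annotation pairs 7244 of them with 1 gene symbol and 1 with several, and 3683 have no annotation row. Through the gene identifier, 5498 probe sets matched 1 gene of the RefSeq R64 table, and 1746 belong to genes of another organism, since this array also carries probe sets of fission yeast. No genome build is named for the deposited table, and no coordinates are given. The RefSeq table was used only for names, gene lengths and the order of genes, which was taken from its start positions. Where several probe sets read a gene (47 genes), the brightest over all 6 arrays was kept, which left 5449 genes.

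Values were transformed to log2(intensity + 32), and reported log2 fold changes are on that scale, which understates the change of dim genes. Fold values set beside them are ratios of mean intensities. Array medians over the tested genes lay between 7.56 and 7.59, so no further normalization was applied. The difference between the strains was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The moderated test had 8.91 degrees of freedom. The precision is limited by the number of arrays. Background was read from the probe sets of the other organism, whose 99th percentile was 3.7. All 6 arrays lay above it for 5305 of the genes, and at or under it for 71. Every gene past the threshold lay above it on all 6 arrays.

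A total of 52 gene lists was fixed before the data were examined, and 50 had 3 or more measured members. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry run beside it. fry tests whether a list's genes move, on balance, in a given direction and does not compare them with other genes. Genes near chromosome ends were planned as those within a set distance of the end. Distances were not computed from the RefSeq positions. The stand-in written for a table without usable coordinates was used, which takes the outermost 10 protein-coding genes of each chromosome end. Genes named in the text are the 12 largest rises and 12 largest falls past the threshold, up to 4 passing members of each list whose shift passed and of the chromosome-end genes, and every measured member of the H2A and H2B, strain marker and silent mating lists. Genes named outside this rule are marked as such.

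The procedure was tested on 20 simulated data sets with the means and spreads of the 5449 genes and 200 changed genes in each. For this comparison it recovered 36.9% of simulated log2 changes of 0.15, 98.6% of those of 0.3 and 99.9% of those of 0.6, and 5.64% of calls were false. The simulation drew genes independently of each other, so it does not cover genes that vary together between arrays.

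Alternatives covered scaling, pseudocount, a filter on dim genes, the replicate number as a block, the variance prior, array weights, the choice of probe set, the threshold and leaving out each array. Control, reporter and unannotated probe sets, and those of the other organism, were left out of the gene tests. Figures were drawn with matplotlib 3.10.9.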

Results

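Expression in a histone H2B K111A mutant of budding yeast was compared with that in its wild type, 3 arrays each, to find the genes whose mRNA level the substitution affects. Mean intensity over all probe sets lay between 146.4 and 148.2 on the 6 arrays, and arrays of the same strain correlated at 0.997 to 0.998 over genes on the log2 scale. Some control and reporter probe sets also differed in mean between the strains. On 14 pairs of probe sets for Bacillus transcripts, which are commonly added to RNA before labelling, the log2 ratio of the 5' to the 3' probe set was -0.56 ± 0.07 in wild type and -0.41 ± 0.06 in the mutant (SD, n = 3 each). The ratio was higher in the mutant for 11 of these 14 pairs. On 11 pairs for yeast genes the same ratio was -1.06 ± 0.09 and -1.07 ± 0.05 (exact permutation p = 1), with 3 pairs higher and 8 lower in the mutant, and on 12 pairs for hybridization controls -0.42 ± 0.02 and -0.39 ± 0.03 (exact permutation p = 0.2). All 17 ribosomal RNA control probe sets were higher on average in the mutant, with mean log2 values of 6.69 ± 0.09 against 6.43 ± 0.12 (SD, n = 3 each). On 3 probe sets of a yeast reporter sequence, singled out after their values were seen, the mean log2 value was 8.49 ± 0.03 in the mutant against 9.15 ± 0.37 in wild type, although limma called none of the probe sets outside the tested genes. These sets read 818, 522 and 910 on wild-type array 3, against 568 to 608, 268 to 285 and 558 to 606 on wild-type arrays 1 and 2. The sources do not say whether the sequence is a marker that differs between the strains. The Bacillus, ribosomal RNA and reporter differences each had an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 arrays allow.

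Many genes differed between the strains, and nearly all by little. Of 5449 genes, 377 rose and 415 fell in the mutant, together 792 or 14.5%. On the log2(intensity + 32) scale, which understates the change of dim genes, the median change among them was 1.14-fold. On that scale 8 changed by 1.5-fold or more, of which 7 fell. The largest fall was in AFB1, from 129 ± 4.69 to 52.2 ± 2.72 (SD, n = 3 each), and the largest rise in PIR3, a cell wall protein, from 187 ± 14.4 to 361 ± 17.8. At an unadjusted p under 0.05 there were 1729 genes, where 272 are expected by chance, and the strains' values did not overlap in 36.7% of genes, where chance gives 10%. The count fell to 477 without wild-type array 1, and to 303, 455 and 213 without mutant arrays 1, 2 and 3. It was 489 with a pseudocount of 1.

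**Figure D1:**
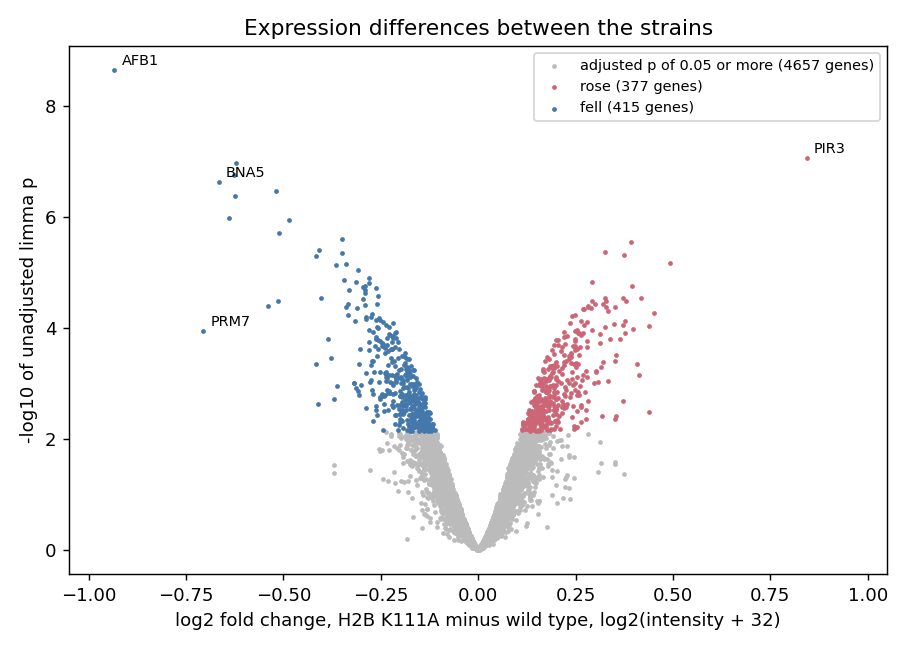
Log2 fold change of each of 5449 genes (x axis, mutant minus wild type) against the -log10 of its unadjusted limma p (y axis), with the 377 genes that rose and the 415 that fell in colour. Most coloured points lie close to 0 on the x axis, and AFB1 at -0.93 and PIR3 at 0.84 lie farthest out.

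The largest rises after PIR3 were in genes with varied roles. GPH1, glycogen phosphorylase, rose 1.52-fold, from 110.97 ± 9.46 to 169 ± 7.65 (SD, n = 3 each, adjusted p = 0.00197). RTC3 rose from 101 ± 23.5 to 147 ± 5.72 and GCY1, a glycerol dehydrogenase, from 187 ± 27.2 to 258 ± 12.1. The vacuolar transporter VMR1 rose 1.40-fold (adjusted p = 0.00128), the mitochondrial phosphate carrier PIC2 1.39-fold, the peroxisome biogenesis factor PEX19 1.37-fold and COQ6, of coenzyme Q synthesis, 1.35-fold. The kinase gene YPK2 rose from 35.7 ± 6.85 to 57.6 ± 6.65. COS6, a member of a subtelomeric family of near-identical genes whose probe sets can read more than their own gene, rose 1.41-fold. YBR085C-A rose 1.40-fold and YNR068C 1.48-fold. The calls of RTC3 and GCY1 were lost without mutant array 1 (adjusted p = 0.0704 and 0.0544) and without mutant array 3 (0.107 and 0.0622), that of RTC3 also without mutant array 2 (0.0793), and that of YPK2 without mutant array 3 (0.0504).

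The largest falls were of 12 genes with varied roles. AFB1 was 2.47-fold lower in the mutant (adjusted p = 1.24e-05). BNA5 and BNA2, enzymes that make NAD from tryptophan, were 2.22-fold and 1.57-fold lower, and NRT1, a transporter of nicotinamide riboside, was 1.77-fold lower. PRM7, a pheromone-regulated gene, fell from 310 ± 57.5 to 176 ± 18.3 (SD, n = 3 each). PHM6, a phosphate-regulated gene, was 1.75-fold lower, the purine-cytosine permease family gene FCY21 1.87-fold, the phospholipase gene PLB2 1.69-fold, NCA3 1.69-fold and HOT13, of the mitochondrial intermembrane space, 1.67-fold. TBF1, an essential DNA-binding protein of telomeric repeats and of gene promoters, fell from 106 ± 4.05 to 66.7 ± 4.12 (adjusted p = 0.000691). YDR222W was 1.58-fold lower. None of the 12 largest falls lost its call when any array was left out.

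**Figure D2:**
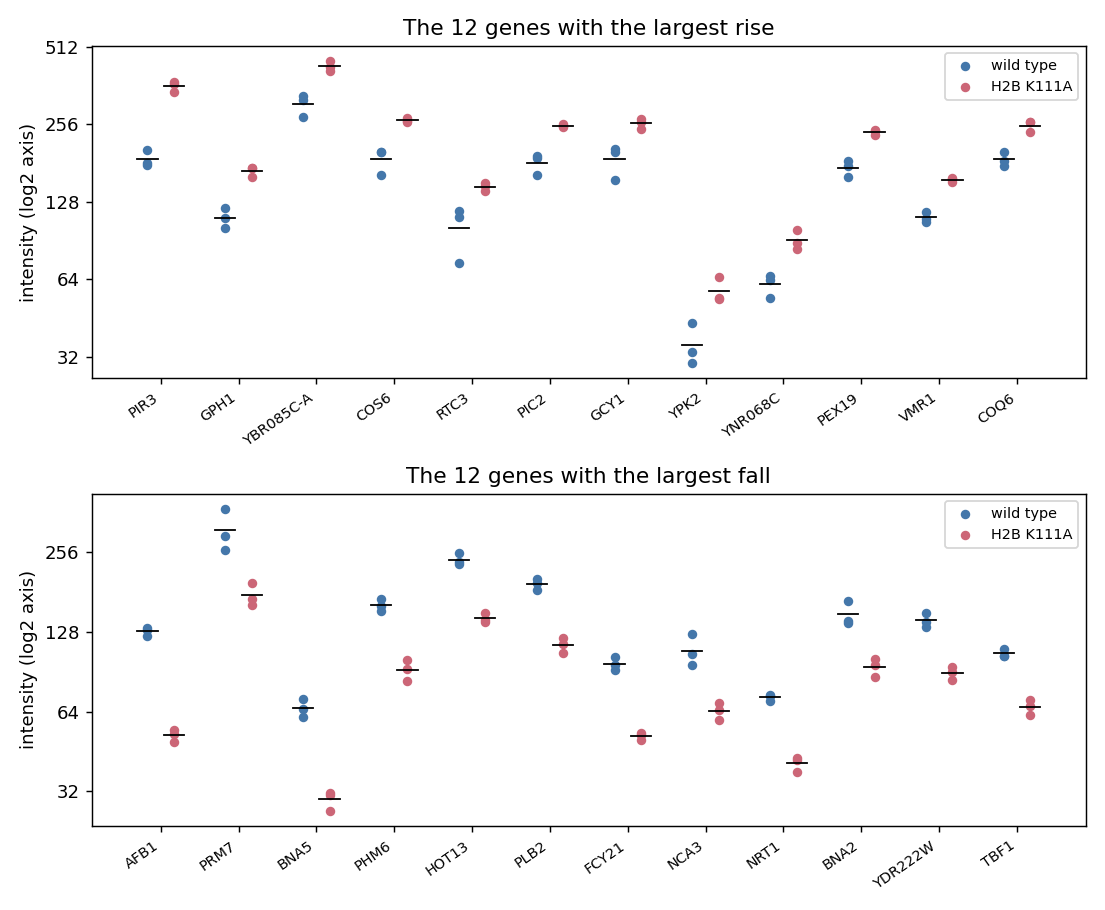
Intensity (y axis, log2 scale) of the 12 genes with the largest rise and the 12 with the largest fall, with a point per array and a bar at the mean of each strain (n = 3). The points of the strains do not overlap for any of these genes, and AFB1 shows the widest gap, with means of 129 and 52.2.

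In the list of NAD and nicotinic acid metabolism, the members past the threshold were lower. Of 14 measured, 6 fell and none rose over all genes tested. Adjusted over the list alone, 7 fell and 1 rose, NMA2, named after its value was seen. Besides BNA5, NRT1 and BNA2, BNA6 fell from 258 ± 13 to 213 ± 3.87 (SD, n = 3 each). The median log2 change of the list was -0.07 and its mean -0.14, camera at the preset correlation gave an adjusted p of 0.0304, and fry an adjusted p of 0.0171, the only list past fry's threshold. With an estimated correlation the adjusted p was 0.812. The preset-correlation call was lost without wild-type array 2 (adjusted p = 0.0544) or wild-type array 3 (0.0510).

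In the phosphate regulon 5 of 19 measured genes fell and none rose over all genes tested. Adjusted over the list alone, 5 fell and 1 rose, VTC1. The phosphate transporter gene PHO89 fell from 298 ± 39.6 to 214 ± 8.72, GIT1, which takes up glycerophosphoinositol, from 166 ± 16.9 to 119 ± 7.09, and SPL2 from 526 ± 45.4 to 434 ± 28.5 (SD, n = 3 each). Of 28 nitrogen catabolite genes 8 fell and none rose over all genes tested. Adjusted over the list alone, 10 fell and 1 rose, UGA1. VTC1 and UGA1 were named after their values were seen. The repressor gene DAL80 was 1.64-fold lower, UGA4, a GABA permease, 1.40-fold, the oligopeptide transporter OPT2 1.35-fold and DAL2, of allantoin use, 1.29-fold. Camera at the preset correlation gave adjusted p = 0.0268 for the phosphate and 0.0304 for the nitrogen list, and both had adjusted p = 0.812 with an estimated correlation. The phosphate call was lost without wild-type array 3 (adjusted p = 0.0683), and the nitrogen call without wild-type array 1 (0.0536) or mutant array 2 (0.0932). Leaving out an array also ended the calls of PHO89, SPL2 and DAL2, with adjusted p up to 0.0542 (mutant array 3 out), 0.0915 (mutant array 1) and 0.0735 (mutant array 3).

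Of 68 measured genes of the general stress response 19 rose in the mutant and none fell, 20 when adjusted over the list alone. Their median deviation was -0.11 on wild-type array 3, against -0.02 and -0.01 on wild-type arrays 1 and 2 and 0.004 on mutant array 2, and the list's mean log2 change was 0.11, or 0.07 without wild-type array 3. Besides GPH1 and GCY1, the hexokinase gene HXK1 rose from 402 ± 31.0 to 529 ± 22.6 and GLC3, the glycogen branching enzyme, from 99.2 ± 17.6 to 137 ± 6.40 (SD, n = 3 each). Of 30 genes of heat shock proteins and chaperones 7 rose and none fell, 8 when adjusted over the list alone. CUR1 rose 1.42-fold, the mitochondrial chaperones HSP78 1.30-fold and MDJ1 1.28-fold, and SSA3 1.23-fold. Camera at the preset correlation gave adjusted p = 1.44e-05 for the stress and 0.0151 for the heat shock list. With an estimated correlation both had adjusted p = 0.812. The heat shock call was lost without wild-type array 3 (adjusted p = 0.0938) or mutant array 1 (0.141). Leaving out an array also ended the calls of GCY1, GLC3, CUR1 and MDJ1, with adjusted p up to 0.0622 (mutant array 3 out), 0.0805 (mutant array 1), 0.109 and 0.121 (mutant array 3).

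Some respiratory genes rose by small amounts. Of 42 genes of oxidative phosphorylation 6 rose and none fell, and 6 did when adjusted over the list alone. ATP17, a subunit of the ATP synthase, rose from 520 ± 33.0 to 662 ± 7.17 and CYT1, cytochrome c1, from 475 ± 7.0 to 603 ± 10.3 (SD, n = 3 each). NDI1, the internal NADH dehydrogenase, rose 1.23-fold and COX13, of cytochrome c oxidase, 1.15-fold. In the TCA cycle list 3 of 20 rose, SDH1 by 1.13-fold, SDH2 by 1.12-fold and the pyruvate carboxylase gene PYC2 by 1.11-fold, and 8 rose when adjusted over the list alone. Camera at the preset correlation gave adjusted p = 0.00644 and 0.0170, and with an estimated correlation both had adjusted p = 0.812. Without mutant array 1 neither call held (adjusted p = 0.169 and 0.147), and without wild-type array 3 the TCA call did not (0.0701). Leaving out an array also ended the calls of COX13, PYC2, SDH1 and SDH2, with adjusted p up to 0.0741 and 0.0885 (mutant array 3 out) and 0.0807 and 0.118 (mutant array 1); for SDH1 each of the 6 arrays did so.

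Some amino acid genes rose. Of 52 genes of amino acid biosynthesis under Gcn4, 10 rose and none fell, 12 when adjusted over the list alone. ARG1, ARG3 and ARG4, of arginine synthesis, rose 1.29-fold, 1.27-fold and 1.23-fold, and LYS2, of lysine synthesis, rose from 303 ± 3.12 to 378 ± 10.8 (SD, n = 3 each). In the sulfur and methionine list 6 of 36 rose and 1 fell, 11 and 3 when adjusted over the list alone. The sulfate permease gene SUL2 rose 1.36-fold, the regulator MET28 1.43-fold, and MET1 and MET10, of sulfite reduction, 1.27-fold and 1.22-fold. The gene that fell was GSH1, of glutathione synthesis, named here after its value was seen. Camera at the preset correlation gave adjusted p = 0.00252 and 0.0166, and both had adjusted p = 0.812 with an estimated correlation. The sulfur call was lost without wild-type array 3 (adjusted p = 0.0683), and the calls of SUL2 and MET28 without mutant array 3 (0.0635 and 0.104) among others.

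Members of the ribosomal protein list that passed mostly rose, and those of the ribosome biogenesis list mostly fell, though most members of either did not pass. Of 128 genes of cytoplasmic ribosomal proteins 23 rose and 1, RPL2A, named after its value was seen, fell; adjusted over the list alone 26 rose and 3 fell. RPS19A rose from 1036 ± 61.1 to 1270 ± 113, RPL17A from 1150 ± 34.1 to 1375 ± 77.7, RPS10B 1.20-fold and RPL26B 1.19-fold (SD, n = 3 each), though most of these genes have a near-identical copy that a probe set may also read. Of 87 ribosome biogenesis genes 9 fell and 2 rose, 6 and 2 when adjusted over the list alone. The export adaptor NMD3 and the helicase DBP8 were 1.20-fold and 1.21-fold lower, UTP7 1.16-fold and ARX1 1.15-fold. NOP56 and UTP10, named after their values were seen, rose. Of 27 genes of RNA polymerases I and III 8 fell and 2 rose, with the same counts when adjusted over the list alone. RPC17 was 1.24-fold lower, RPC25 1.19-fold, RRN10 1.19-fold and RRN9 1.16-fold, while RPC82 and RPA190, named after their values were seen, rose. Camera at the preset correlation gave adjusted p = 0.00156, 1.53e-05 and 0.0457 for the 3 lists, and all had adjusted p = 0.812 with an estimated correlation. With quantile normalization the ribosomal protein and polymerase lists did not pass (adjusted p = 0.120 and 0.0514), and the mean log2 change of the ribosomal protein list was 0.028 in place of 0.048. Without wild-type array 2 that mean was 0.074, and without wild-type array 3 the biogenesis mean was -0.046 in place of -0.075. The arrays of the strains overlapped for both lists (exact permutation p = 0.3 and 0.2). The ribosomal protein call was also lost without mutant array 1 (0.0896), and the polymerase call without wild-type array 1 (0.0636), wild-type array 3 (0.210), mutant array 1 (0.120) or mutant array 3 (0.0898). Leaving out mutant array 3, among others, ended the calls of RPS19A (0.0885), RPL26B (0.0622), NMD3 (0.0620), UTP7 (0.114), ARX1 (0.1499), RPC17 (0.0697) and RPC25 (0.0670), and those of RRN9 and RRN10 ended at up to 0.0634 (mutant array 1) and 0.101 (mutant array 2).

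In all, 12 of the 50 tested lists passed camera at the preset correlation, 7 higher and 5 lower, and 0 passed with an estimated correlation, where the lowest unadjusted p was 0.0449, for the NAD list. The adjusted p of 0.812 that the 12 lists share is a tie made by the adjustment. Their unadjusted p in camera with an estimated correlation ran from 0.0449 to 0.454, the latter for ribosomal proteins. Without wild-type array 3 only 6 passed. The count of shifted lists was not larger than in mixed groups of the arrays, since other splits of the 6 arrays into 3 and 3 gave between 1 and 13 lists. For 5 of the 12 lists, among them ribosome biogenesis and ribosomal proteins, the arrays of the strains overlapped. For the other 7, among them the NAD, phosphate, nitrogen, stress and Gcn4 lists, they did not, with an exact permutation p of 0.1. Overlap was examined only for lists that camera had already picked on the same arrays, so its absence is not independent support.

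**Figure D3:**
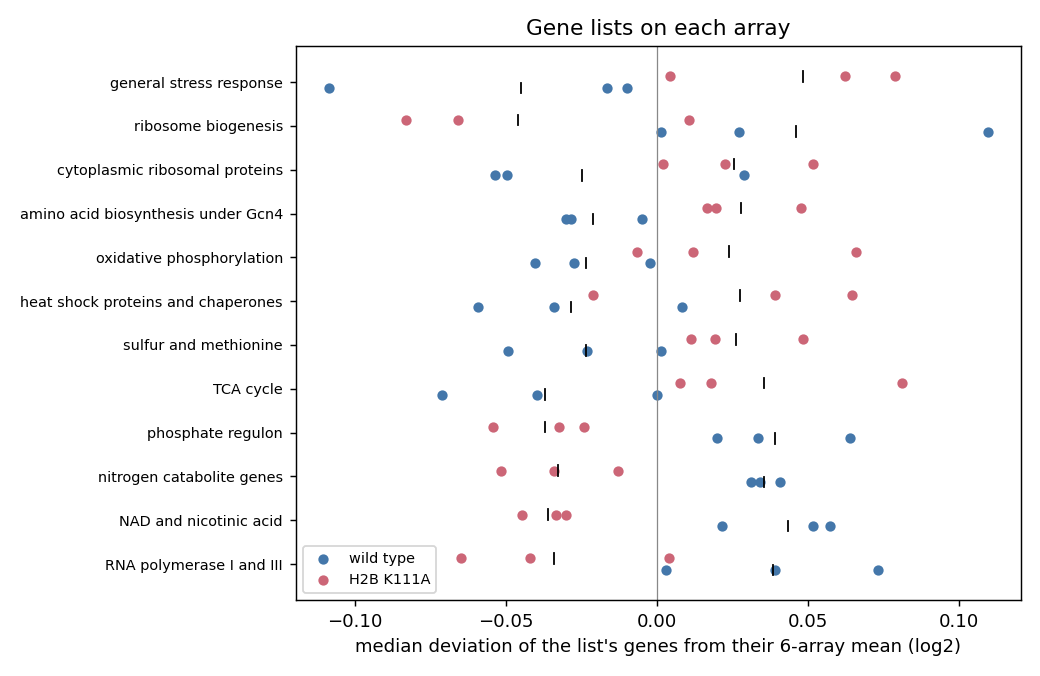
For each of the 12 lists past camera at the preset correlation, the median deviation of its genes from their mean over the 6 arrays (x axis, log2) on each array, with a bar at the mean of each strain (n = 3). The strains' points overlap in 5 of the 12 lists.

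The measured genes near chromosome ends, where silencing acts, did not shift as a group. Of 320 genes, the outermost 10 of each chromosome end, 235 were measured, of which 19 rose and 20 fell. The fixed list of 8 Y' helicases had no measured member, so the outcome covers only the genes that could be read. The median log2 change was -0.0045, and camera gave p = 0.803 (0.845 with an estimated correlation). The share past the threshold was 16.6% against 14.4% of other genes (Fisher's exact test, two-sided, p = 0.345). SNO3 fell from 98.2 ± 6.37 to 65.6 ± 2.08 and BAS1, a regulator of purine and histidine genes, from 247 ± 34.2 to 178 ± 23.9 (SD, n = 3 each), beside PHO89 and GIT1. The SNO3 probe set is of the kind with shared sequence, so its signal may come in part from another gene. The BAS1 call was lost without wild-type array 1 (adjusted p = 0.0705) or 2 (0.0652), or mutant array 1 (0.0856) or 3 (0.103). No chromosome shifted in limma's camera, with chromosome medians between -0.012 and 0.012 and adjusted p of 0.938 or more.

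At the silent mating loci, HMLALPHA1 was at background in both strains, at 1.30 ± 0.40 and 1.60 ± 1.28 (SD, n = 3 each). HMRA1, whose sequence is also present at the active mating locus of MATa cells, read 175 ± 7.98 in wild type and 153 ± 14.6 in the mutant (adjusted p = 0.0865), and HMRA2 144 ± 12.9 and 136 ± 11.4. The HMRA2 probe set is also of the kind with shared sequence. The HMRA1 difference passed without mutant array 2 (adjusted p = 0.0302). The mRNA of the mutated histone and its partners did not pass the test. HTB1 read 1280 ± 40.5 and 1204 ± 50.5 (adjusted p = 0.192), HTA1 1579 ± 42.0 and 1677 ± 105.3, and HTA2 1207 ± 54.2 and 1260 ± 19.8. The HTA2 probe set is of the kind with shared sequence, so its signal may come in part or whole from another gene. HTB2, the second H2B gene, read only 3.90 ± 0.17 and 3.73 ± 0.25, close to background in both strains. Its reading does not show whether the gene is missing from both strains or is unread by its probe set. A point substitution need not change the mRNA level, so these values do not check the strain labels. Of the strain marker genes LYS2 rose, and LEU2 fell from 318 ± 3.23 to 265 ± 14.6 (adjusted p = 0.00971). URA3 read 466 ± 9.38 and 448 ± 5.77, CAN1 214 ± 6.93 and 207 ± 5.55, LYP1 584 ± 17.5 and 606 ± 11.2, and ADE2 107 ± 8.94 and 115 ± 1.45, none past the threshold. MET17 read 1088 ± 25 and 1188 ± 29.1 (adjusted p = 0.0502) and HIS3 733 ± 26.2 and 810.4 ± 31.4 (0.0548), and both passed with quantile normalization (0.0376 and 0.0339).

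**Figure D4:**
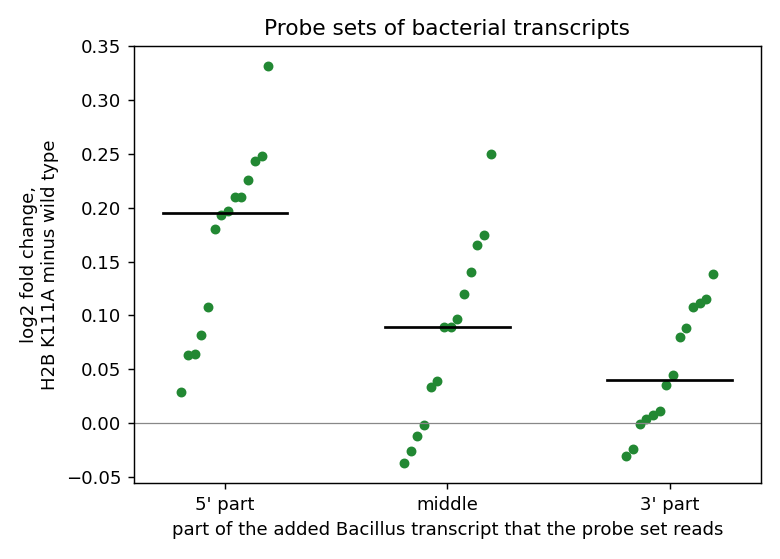
Log2 fold change, mutant minus wild type (y axis), of 42 probe sets for Bacillus transcripts, by the part of the transcript they read (x axis), with a bar at the median. The 5' probe sets have a median of 0.20 and the 3' probe sets 0.04.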

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

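No result met the rules set for an outlying sample, a difference between contrasts or a signal outside the tested genes. Groups of 3 were not tested for outliers. Of the control, reporter, unannotated and other-organism probe sets limma called 0 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 47 of 166 control and 5 of 47 reporter sets. There were also 187 of 3470 unannotated and 75 of 1747 other-organism sets (the 1 set with several symbols included), against 1729 of 5449 genes. The adjustment ran over all these sets together, so the 0 does not show that the control sets were alike in the strains. The tests of the bacterial transcripts, of growth state, of intensity matching and of the ribosome gap over other splits were chosen after related values were seen.

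A pattern to follow up is the 792 genes past the threshold with small changes. The real split gave 792 genes and the highest of the other 9 gave 1; 1 of the 10 splits reached the real count, and 10 splits are too few for a share under 0.05. A difference in labelling or hybridisation stays open, since 28.6% of 42 Bacillus probe sets (12, all higher in the mutant; exact 95% interval 15.7% to 44.6%) passed the p cutoff of the genes, against 14.5% of genes, although these sets read few transcripts and are not independent. The 5' to 3' ratio differed by 0.14 on the Bacillus pairs, by 0.03 on hybridization controls (exact permutation p = 0.2) and by -0.01 on yeast gene pairs (exact permutation p = 1). The yeast pairs moved both ways, from -0.22 for RIP1 to 0.20 for WBP1, both named after their values were seen, and some read the same gene, so their mean does not argue against such a difference. The Bacillus pairs moved both ways too, from -0.06 to 0.38, with 11 of 14 higher in the mutant. Gene length could account for part, since among the genes past the threshold log2 fold change followed gene length with a Spearman rho of 0.10 (0.105, bootstrap 95% interval 0.036 to 0.169). The largest bacterial change was 0.33 on the log2 scale, against -0.93 for AFB1 and 0.84 for PIR3. On the bacterial values alone, small changes are the part most open to a difference in labelling or hybridisation. The 3 reporter probe sets differed by -0.66 in mean log2 value. As they may read a strain marker, they do not tell how large a change labelling or hybridisation could make. That size was not settled. An effect of the histone substitution itself also stays open.

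The opposite shifts of ribosomal protein genes (median 0.05) and ribosome biogenesis genes (-0.09) form the next pattern. Intensity-dependent scaling and gene length are argued against as the whole cause, as far as genes outside both classes show them. Random lists of such genes matched on intensity had medians of -0.008 (for ribosomal proteins) and -0.009 (for biogenesis). Those matched on length had -0.008 and 0.006. The gap of 0.14 between the medians of the classes lay above the upper limits of 0.0299 and 0.0195 for these lists (10000 each). The lists drew genes independently, so these limits do not cover genes that vary together between arrays. Intensity may account for part, since quantile normalization, a planned setting, cut the mean ribosomal protein shift from 0.048 to 0.028 and ended its call (adjusted p = 0.120). The gap under it, computed after seeing the data, was 0.103. The gap itself does not stand clear of variation between arrays, as 2 of the 10 splits, the real one included, gave a gap as large and the highest other was 0.158; 10 splits are too few for a share under 0.05. A change of growth rate moving both classes together predicts the same sign. The rule first written would have excluded it, since intervals from resampling genes excluded 0 for both classes (0.036 to 0.071 and -0.104 to -0.076). It was made stricter after that was seen, because resampling genes treats them as independent. As the arrays of the strains overlapped for both classes, the gap of 0.14 (0.140) leaves it undecided. With quantile normalization the arrays separated for ribosomal proteins, at -0.01 ± 0.006 in wild type and 0.01 ± 0.010 in the mutant (SD, n = 3 each, exact permutation p = 0.1), and still overlapped for biogenesis genes (exact permutation p = 0.2). Differences in culture state between samples, unrelated to the histone, therefore stay open.

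The same holds for the count of shifted lists. The real split gave 12 lists and the highest other split 13, and 3 of the 10 splits gave as many as the real one, too few splits for a share under 0.05.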

How the results depend on the processing

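The combination of quantile normalization with wild-type array 3 left out, the outermost 5 and 20 genes, the array medians for the list shifts, and quantile normalization for the ribosomal gap were chosen after seeing the data. The distances of 10 and 30 kb from chromosome ends were not run, a choice made because no genome build is named for the deposited table. The outermost 10 genes are the reported setting. The 792 genes past the threshold became 8 (1 up, 7 down) with a change of 1.5-fold or more, 0 (0 up, 0 down) in limma with 2-fold or more on the log2(intensity + 32) scale, where 1729 had an unadjusted p under 0.05, and 159 (70 up, 89 down) at an adjusted p under 0.01, by construction of those thresholds. A pseudocount of 1 gave 489 (232 up, 257 down); the cause was not tested. Leaving out an array gave 213 to 559 genes, 91 to 271 up and 122 to 294 down, with fewer samples in each fit. The other settings gave 646 to 904 genes. Each of the 792 genes kept its sign wherever it was tested, except that 774 of 776 did when probe sets with shared sequence were left out. The sign is little support. The block and the variance prior leave the log2 fold change as it is. A gene whose strains do not overlap cannot change sign when an array is left out. With the replicate number as a block 346 genes passed (170 up, 176 down), of which 342 were among the 792. The numbers share no stated day or batch, the deviations of same-numbered arrays correlated at -0.23, -0.06 and -0.17, and no wild-type array correlated best with its own number. All 12 list calls held with the block, which made 13 in all. The 12 list shifts became 0 with an estimated correlation, for a cause not tested, and 6 to 12 with an array left out. The chromosome-end genes and the chromosomes passed under no setting run, with p from 0.437 to 0.989 for the former, whose median changed sign in some settings without a call. Among the named genes, leaving out an array ended 85 calls, made 1 and left 400 as they were, the block ended 10, and quantile normalization made 2. Signal over background limits HMLALPHA1, above background on 0 of 6 arrays, and HTB2, above it on 4 of 6. For HTB2 weak detection and a missing gene were not told apart.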

Other observations

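The test of the middle sporulation genes was chosen after related list values were seen. Several lists that did not pass held members that changed. Of 8 measured COS genes, a subtelomeric family, 4 rose and none fell, COS4 from 614 ± 25 to 760 ± 10.9, COS7 from 134 ± 11.9 to 177 ± 16.9 and COS8 from 188 ± 15.7 to 241 ± 3.80 (SD, n = 3 each) beside COS6, though their near-identical sequences leave it uncertain which member was read (camera adjusted p = 0.0639, and 0.812 with an estimated correlation). Of 36 genes of the DNA damage response 6 rose and 2 fell, with HUG1 1.30-fold and MGT1 1.27-fold higher and TOS2 1.39-fold lower (camera adjusted p = 0.0639). These genes were named after their values were seen.

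Of 48 genes of meiosis and sporulation, which are largely off in growing cells, 8 fell and 1 rose (camera adjusted p = 0.0863). IME1, the inducer of meiosis, fell from 24.8 ± 2.48 to 15.9 ± 0.85 and SPO1 from 41.1 ± 1.74 to 27.7 ± 1.12, while IME2 rose from 28 ± 1.92 to 36.1 ± 2.18 (SD, n = 3 each). In the list of the unfolded protein response 3 of 14 fell and none rose, ERO1 from 818 ± 29.5 to 704 ± 24.3, SIL1 1.19-fold and EUG1 1.11-fold (camera adjusted p = 0.529). The genes of these lists were also named after their values were seen.

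A hypothesis from the lower NAD genes is stronger repression by a complex that also keeps middle sporulation genes off in growing cells. Of 30 measured middle sporulation genes 4 fell and none rose, with a median log2 change of -0.03. Over all 5449 genes, limma's camera gave this list p = 0.145, and an exact permutation test of its median per array p = 0.2, so their shift did not pass. Their median intensity was 17.8, too low for this to exclude the hypothesis, which may still hold.

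Neighbouring genes showed a weak tendency to change together. Over 5017 pairs of adjacent measured genes the Spearman correlation of log2 fold changes was 0.0587, against a median of 0.0025 in 1000 shuffles within chromosomes (p = 0.001, the smallest they can give). It was 0.074 for divergent, 0.062 for tandem and 0.039 for convergent pairs. Among pairs with both genes past the threshold, 52 changed in the same direction and 53 in opposite directions, so the tendency was not seen there. This is a correlation across genes, which are not independent replicates. The shuffles moved genes and not arrays, so their p does not cover variation between arrays. Other splits of the arrays were not run for this correlation, so it is not tied to the strains. Probe sets that read a neighbour's transcript were not tested as its cause.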
